A study of Mus musculus with 18 samples.

How the data were processed

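Testes of CD1 mice, an outbred laboratory strain, were taken at 17 days, at 22 days and from adults, per the labels. Per the labels' protocols, cytoplasmic extracts were spun through sucrose gradients of 10 to 30% that were collected as 17 fractions, and RNA was pooled from fractions 2 to 8 for the RNP sample and from fractions 11 to 17 for the polysome sample. RNPs (ribonucleoprotein particles) are complexes of RNA and protein that sediment slowly, and polysomes are messenger RNAs that carry several ribosomes and sediment fast. RNA was extracted with Trizol, turned into biotin-labelled cRNA and hybridised to Affymetrix mouse arrays of 22690 probe sets, per the labels' protocols.

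The deposited table holds 1 intensity value per probe set and array, on a linear scale, which the authors obtained with MAS5 per the submitters' processing notes. The version and the scaling settings are not given in the sources used here. The values themselves show a scaling that the authors had already applied: the mean of each array after trimming 2% at each end lay between 150 and 150.1. Array medians ran from 42.8 to 59.5, a ratio of 1.39, which is under the limit of 1.5 above which the arrays were to be quantile normalized, so the values were used on the authors' scale. The highest value was 12560 and 7 values were 0. How the replicates were made is given only as a biological replicate number. Nothing states that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical in part. Replicates of a group correlated across probe sets at 0.859 to 0.981.

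Values were analysed as log2(value + 15), where 15 is the 25th percentile of all values, and the 64 control probe sets were kept out of the tests. A probe set was tested if at least 3 of the 18 arrays lay above 51.6, the 50th percentile of all values, which left 14066. Fold changes are on the log2(value + 15) scale and understate the changes of genes with low values. Names came from the platform annotation, in which 20393 probe sets had 1 gene symbol, 691 had several and 1606 had none. Of the named ones, 20364 were found by Entrez ID in a RefSeq gene table of assembly GRCm38.p6, 0 needed a new symbol and 29 were not found. Of the tested probe sets, 12972 named exactly 1 gene, for 8713 genes. No coordinates are given, since the genome build behind the probe sets is not given in the sources used here.

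All 18 arrays entered a single limma model (limma 3.58.1 in R 4.3.3) with 6 groups of 3 arrays, fitted with lmFit and eBayes with a variance trend. It had 12 residual degrees of freedom and 6.51 prior degrees of freedom. The contrasts were RNP minus polysome at each age, the change of that difference between ages (the ratio contrasts) and the later minus the earlier age within each fraction. Tests were two-sided with Benjamini-Hochberg adjustment over the tested probe sets at 0.05, and errors printed with log2 differences are standard errors of the limma model unless stated otherwise. Every adjusted p-value is from limma. A switch of fraction required an adjusted p under 0.05 in both fraction contrasts and in the ratio contrast, with opposite signs. With arrays, the number of replicates limits the precision.

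The groups share replicate numbers in the labels. Deviations from the group means were correlated between the fractions of an age at 0.197 to 0.585 in all 9 pairs of arrays with the same number. At 22 days and in adults each array correlated below 0 with those of other numbers in the other fraction. Deviations within a group of 3 sum to 0, so a positive value with the own number pulls the others below 0. Their sign is therefore not separate evidence of pairing. At 17 days the pairing is less clear, since array 3 correlated at 0.345 with another number and at 0.337 with its own, and array 1 at 0.264 and 0.310. The numbers were taken to pair the fractions within an age, and a limma model with the pair as a block (6 residual degrees of freedom) was also fitted. It is given where it changed the call of a named gene or list test in the fractions or ratios, and beside some other values. Across ages the correlations of same-numbered arrays ran from -0.29 to 0.37, so the numbers do not pair ages. The arrays of 17-day replicate 2 and adult replicate 1 correlated at 0.375 on polysomes and 0.408 in RNPs, as high as some pairs within an age. These 4 arrays were left out together in a setting chosen after the data had been seen. Of them 3 had the highest poly-A control signals of all arrays (337, 335 and 219), while the adult RNP array (107) lay below 3 arrays that were kept.

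Probe sets were named by a rule fixed, with the tests, the gene lists and the other settings, before the data were examined. The rule took probe sets that name 1 gene, pass the threshold and have the 3 arrays of a group all above the 3 of the other group, an order that chance gives for 10% of genes in 3 against 3 (in ratio contrasts the 3 differences by replicate number). These were ranked by the size of the log2 difference with 1 per gene: 6 per direction in fraction contrasts, 10 in the ratio contrast of 17 days and adults, 5 in the other ratio contrasts and 4 in the age contrasts. A further 17 genes were named in every fraction and ratio contrast; Insl3, Oaz3 and Gapdh had no tested probe set of their own, which left 14. Up to 4 members of each list with the smallest p were named. For lists and fixed genes the probe set with the highest mean over all arrays was used.

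The 22 gene lists covered chromatin condensation proteins of spermatids, sperm tail, acrosome and sperm surface, spermatid kinases and regulators, meiosis, germ cell isozymes, spermatogonia, cell cycle, Sertoli cell, Leydig cell, peritubular and smooth muscle, blood and macrophage, epididymis, ribosomal proteins, translation factors, germ cell RNA-binding proteins, proteasome, respiratory chain, glycolysis, chaperonins, endoplasmic reticulum secretory genes, and immediate early genes. Some genes stand on more than 1 list. Lists were tested with limma's camera, which compares a list with all other tested genes, at its preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. RNA quality was compared between fractions with two-sided exact permutation tests, which are unpaired and cannot go below p = 0.1 with 3 arrays against 3, and with exact tests that flip the signs of the 3 differences within pairs, which cannot go below p = 0.25.

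The models were tested on simulated data, made from the spread of these arrays with 200 of the 14066 probe sets changed. For adult fractions limma recovered 39% of log2 1 and 96% of log2 2 changes with 0 false calls. For ratio contrasts it recovered 6% and 83% with 0 (17 days and adults) and 4% and 79% with 2 (22 days and adults). With the block, these were 79% and 100% with 15, 37% and 99% with 10, and 37% and 97% with 10. This cannot show that the numbers pair the real arrays. The real adult fractions gave 5414 calls, so recovery there may differ. An unchanged 17-day fraction contrast gave 0 false calls with and without the block.

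The alternatives were pseudocounts of 1 and 52, no filter and a filter at the 75th percentile, quantile normalization, median centring and quantile normalization within each fraction, no variance trend, only the compared arrays, the replicate block, and leaving out each array in turn. For lists, they were the estimated correlation, limma's fry, and the mean of all probe sets of a gene. Genes named by several probe sets or by none were left unnamed.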

Results

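RNA from 2 gradient fractions of mouse testes was profiled at 3 ages, with 3 arrays for each fraction and age and 18 arrays in all. The study asked which transcripts changed their distribution between RNPs, the slowly sedimenting particles, and polysomes, the ribosome-loaded messenger RNAs, as the testis matured. The intensity filter kept 14066 probe sets for the tests. Log2 differences between fractions are given as RNP minus polysome with their standard errors (SE, n = 3 arrays per group), so that positive values lie on the RNP side. All arrays were scaled to the same trimmed mean, whatever amount of RNA a fraction held. A side is therefore relative to the other transcripts and does not show which fraction held more of a transcript.

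In 17-day testes, the first comparison of the fractions, several transcripts of germ cell specific proteins were far higher in RNPs than on polysomes. Pgk2, the phosphoglycerate kinase of germ cells, was 8.04-fold higher in RNPs (log2 3.01 ± 0.33 SE, adjusted p = 6.55e-06). Its level was 372 ± 23.0 against 34.3 ± 13.1 intensity units (SD, n = 3). Acr, which encodes the acrosomal protease acrosin, was 3.51-fold higher there (1.81 ± 0.27). Crisp2, a secretory protein stored in the acrosome, was 9.02-fold higher (3.17 ± 0.45). On the polysome side lay Sycp3, a component of the synaptonemal complex (-1.12 ± 0.25), the heat shock protein gene Hspa2 (-1.19 ± 0.30) and Clu, which encodes the secreted chaperone clusterin (-2.99 ± 0.69).

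Among the 12 probe sets named by size at 17 days, the RNP side held Bscl2, the lipid droplet protein seipin (4.24 ± 0.50), the complement component C8b (3.72 ± 0.29), the LIM domain gene Fhl4 (3.53 ± 0.34), Ptdss2, a phosphatidylserine synthase (3.47 ± 0.40), the homeobox gene Hoxa4 (3.44 ± 0.22) and Ypel1. The polysome side held Clu, the actin-bundling protein gene Espn, the transcriptional inhibitor Id2 (-2.71 ± 0.24), Uba1y (-2.60 ± 0.29), Ctnnb1, which encodes beta-catenin (-2.55 ± 0.52), and Mdh1, the cytosolic malate dehydrogenase (adjusted p = 0.00756). The call of Mdh1 ended without the RNP array of replicate 1 (adjusted p = 0.0504).

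Lists of sperm tail, acrosome and spermatid regulator genes lay on the RNP side at 17 days, while 0 of 6 chromatin condensation genes passed, also when adjusted over the list alone (median 0.03, camera adjusted p = 0.782). These 6 averaged below the filter value of 51.6 in both fractions at 17 days, so their difference there carries little information. Of 25 sperm tail genes, 10 were higher in RNPs and 0 lower (11 and 1 adjusted over the list alone), among them Meig1 (2.09 ± 0.19), Tcp11 (2.17 ± 0.22) and the outer dense fibre gene Odf2 (2.39 ± 0.30). Camera gave an adjusted p of 3.64e-05, and adjusted p = 0.248 with an estimated correlation. Of 21 acrosome and sperm surface genes, 9 were higher and 0 lower (10 and 0 adjusted over the list alone), including Zpbp (2.16 ± 0.43) and Dkkl1 (2.12 ± 0.46). Camera gave 0.000268, and adjusted p = 0.256 with an estimated correlation. Of 22 spermatid kinases and regulators, 12 were higher and 0 lower, also when adjusted over the list alone, including the kinase gene Haspin (2.75 ± 0.25) and Spata4 (2.51 ± 0.27). Camera gave 1.14e-06, and adjusted p = 0.117 with an estimated correlation. Of 22 germ cell isozymes, 8 were higher and 3 lower, the same numbers as adjusted over the list alone, with Pgam2 at 2.36 ± 0.22 and the tubulin Tubb3 at -1.77 ± 0.21. Their camera call (0.0269) was lost under quantile normalization (0.331) and gave adjusted p = 0.248 with an estimated correlation.

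Of 42 ribosomal protein genes, 18 were higher in RNPs and 0 lower (20 and 0 adjusted over the list alone), for example Rps7 (0.89 ± 0.13), Rps20 (1.20 ± 0.20) and Rplp0 (1.17 ± 0.23). Camera gave 4.38e-07 for this list, 0.11 under quantile normalization, which left the list median above 0, and adjusted p = 0.119 with an estimated correlation. Of 30 genes of the endoplasmic reticulum secretory route, 7 were higher and 0 lower, also when adjusted over the list alone, including the signal peptidase subunit Spcs1 (1.69 ± 0.20) and Srp9 (1.39 ± 0.23). This camera call (0.0273) was lost under quantile normalization (0.11) and gave adjusted p = 0.594 with an estimated correlation.

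Genes of meiosis, of dividing cells and of Sertoli cells, the somatic cells that nurse germ cells, lay on the polysome side at 17 days. Of 25 meiosis genes, 16 were lower in RNPs and 1 higher (17 and 1 adjusted over the list alone), with Tex11 at -1.72 ± 0.27, the cohesin gene Rec8 at -1.39 ± 0.30 and Psmc3ip, the exception, at 1.23 ± 0.21. Camera gave 0.000268, and adjusted p = 0.156 with an estimated correlation. Of 22 spermatogonia genes, 13 were lower and 0 higher (15 and 0 adjusted over the list alone), with Stra8, needed for entry into meiosis, at -2.07 ± 0.23. Camera gave 5.55e-06, and adjusted p = 0.117 with an estimated correlation. Of 31 cell cycle genes, 16 were lower and 3 higher (18 and 3 adjusted over the list alone), with the replication genes Mcm3 at -2.02 ± 0.25 and Pcna at -1.13 ± 0.16. This call held with both correlations (adjusted p = 0.000268, and adjusted p = 0.0462 with an estimated correlation). Of 25 Sertoli cell genes, 12 were lower and 0 higher (14 and 0 adjusted over the list alone), with Nr0b1 at -2.24 ± 0.24 and Rhox5 at -1.58 ± 0.29. Camera gave 3.35e-05, and adjusted p = 0.223 with an estimated correlation.

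Of 37 proteasome subunits, 19 were lower in RNPs and 2 higher at 17 days (23 and 2 adjusted over the list alone), with Psmb4 at -1.69 ± 0.24 and Psma2 at -1.21 ± 0.18. The proteasome call held with the preset (1.05e-05) and with an estimated correlation (adjusted p = 0.0138). Psmd7 on this list had another probe set called in the opposite direction. Of 11 glycolytic enzymes of somatic type, 7 were lower and 1 higher, also when adjusted over the list alone. Ldhb (-2.25 ± 0.28) and Pkm (-1.68 ± 0.25) were lower, and Ldha, the other lactate dehydrogenase subunit, was higher in RNPs (1.82 ± 0.21). Camera gave 0.00381 for glycolysis, and adjusted p = 0.223 with an estimated correlation.

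Over all probe sets, 4044 differed between the fractions at 17 days, 1772 higher in RNPs and 2272 higher on polysomes. Of these, 1069 and 1311 differed by at least 2-fold. With replicate pairs as a block the count was 6108, and without the polysome array of replicate 3 it was 2628. The split depended on scaling and was 1901 to 1927 under quantile normalization, 2152 to 1673 under median centring and 2272 to 1745 under quantile normalization within each fraction. Ldhc, the germ cell lactate dehydrogenase, was slightly higher in RNPs (0.32 ± 0.11, adjusted p = 0.0369), but reversed to -0.18 under quantile normalization (0.182). Its call ended without any of the 6 arrays (adjusted p of 0.0512, 0.112 and 0.0932 without polysome arrays 1, 2 and 3, and of 0.0598, 0.103 and 0.0861 without RNP arrays 1, 2 and 3), with no filter (0.2), with no variance trend (0.187) and without the 4 arrays of 17-day replicate 2 and adult replicate 1 (0.141), a setting chosen after the data had been seen. A further Clu probe set (-2.10 ± 0.59, adjusted p = 0.0125) lost its call without polysome array 2 (0.0584) or RNP array 3 (0.0698). Smcp (0.76 ± 0.33) and Actb, the cytoplasmic actin used as a control gene (-0.33 ± 0.13), missed the threshold (adjusted p of 0.0919 and 0.0658) and passed it with the pair as a block (0.0139 and 0.0492) and with only the compared arrays (0.0255 and 0.0336). Smcp also passed with a pseudocount of 1 (0.0113), and Actb under quantile normalization (-0.88, adjusted p = 4.71e-05) and with the filter at the 75th percentile (0.0484). Prm1, Prm2, Tnp1, Tnp2, Odf1 and Akap4 had 17-day means of at most 36.6 intensity units, with differences from -0.12 to 0.22 that did not pass (adjusted p from 0.746 to 0.997).

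**Figure D1:**
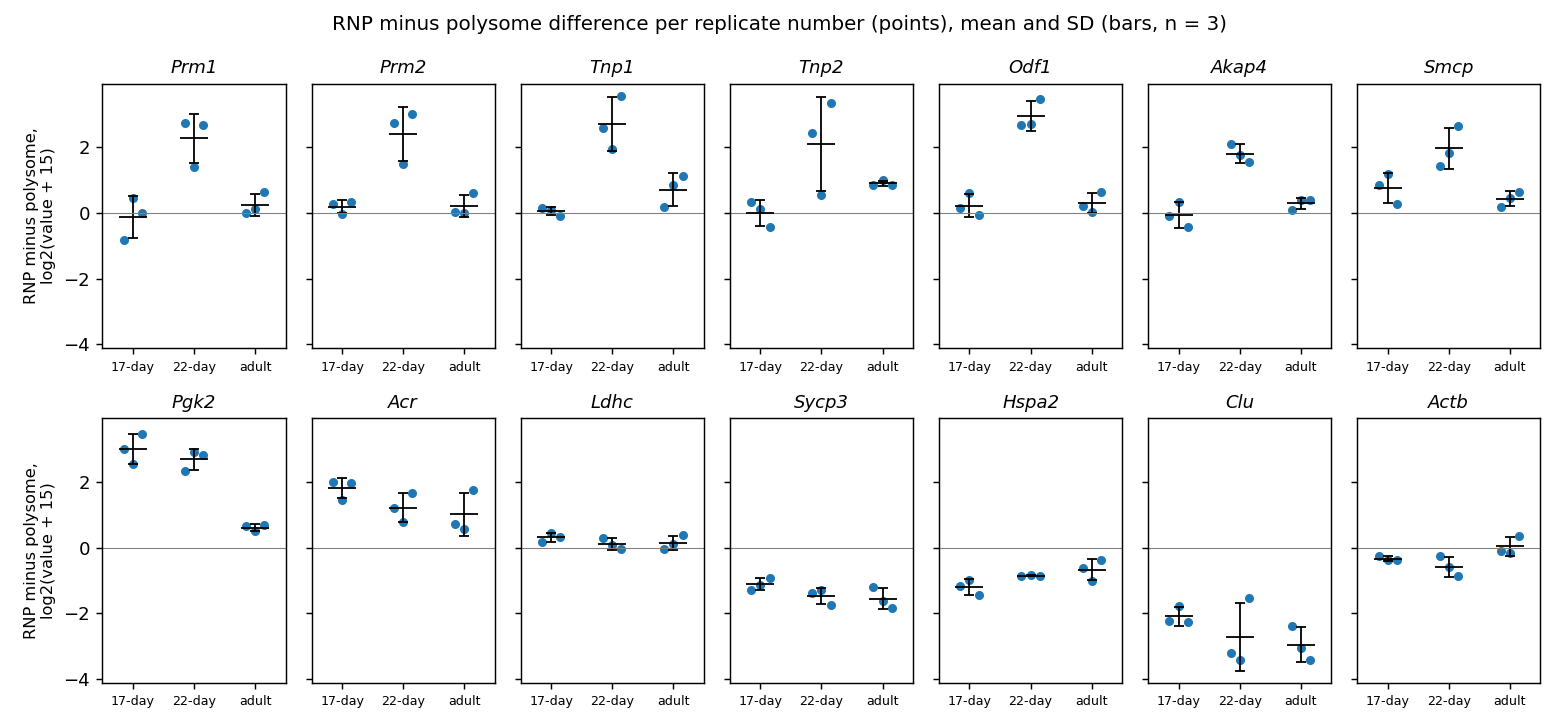
RNP minus polysome difference of log2(value + 15) (vertical axis) at 17 days, 22 days and in adults for 14 genes fixed beforehand; each point is a replicate number and bars give the mean ± SD. Pgk2 averages 3.01 at 17 days, 2.69 at 22 days and 0.61 in adults, and the adult mean of 0.04 for Actb turns to -0.36 under quantile normalization while the 17-day mean of 0.32 for Ldhc turns to -0.18.

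In 22-day testes, transcripts of late spermatid proteins were detected and lay in RNPs. Odf1, a protein of the outer dense fibres of the sperm tail, was 7.75-fold higher in RNPs (adjusted p = 4.65e-05), with levels of 1184 ± 601 against 140.5 ± 93.7 intensity units (SD, n = 3). The protamines, which pack sperm DNA, were higher there too, Prm1 by 2.27 ± 0.80 (adjusted p = 0.033) and Prm2 by 2.41 ± 0.79 (0.022). So was the transition protein gene Tnp1 (2.70 ± 0.78, adjusted p = 0.0112). Akap4, of the fibrous sheath (adjusted p = 0.00395), and Smcp, of sperm mitochondria (1.97 ± 0.33), were higher in RNPs, as were Pgk2 (2.69 ± 0.33) and Acr (1.22 ± 0.27). On polysomes lay Gsta4, a glutathione transferase (-4.11 ± 0.45), Espn (-3.92 ± 0.37), Sparc, a matrix glycoprotein (-3.86 ± 0.84), Amhr2, the receptor for anti-Müllerian hormone (-3.72 ± 0.35), the chromatin protein gene Hmgb2 (-3.51 ± 0.30) and Anxa5 (-3.43 ± 0.27). The RNP side of the genes named by size also held Ptdss2 (3.62 ± 0.40), Dgcr6 (3.09 ± 0.30), C8b (3.03 ± 0.29), Tcte2 (2.94 ± 0.44) and Hoxa4 (2.89 ± 0.22).

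Levels of the late spermatid genes varied between the 22-day arrays, with Prm1 at 1348 ± 1458 in RNPs and 202 ± 205 on polysomes (SD, n = 3). The call of Prm1 ended without polysome arrays 2 (adjusted p = 0.189) or 3 (0.0651) or RNP arrays 1 (0.229) or 3 (0.105). That of Prm2 ended without polysome array 2 (0.138) or RNP arrays 1 (0.157) or 3 (0.0912), and that of Tnp1 without polysome array 2 (0.0813) or RNP arrays 1 (0.088) or 3 (0.0528). With only the compared arrays the calls of Prm1 (0.102), Prm2 (0.0809) and Tnp1 (0.0643) ended, and that of Prm1 also with no filter (0.0595) or a pseudocount of 1 (0.0519). These array omissions and settings were run without the block. With the pair as a block and all arrays, the calls held for Prm1 (1.53e-05), Prm2 (4.63e-06) and Tnp1 (2.95e-06). Each of the 3 genes was higher in RNPs in each 22-day pair. Tnp2 missed the threshold (2.11 ± 0.87, adjusted p = 0.0651), and passed it with the pair as a block (0.000281), without polysome array 1 (0.0237) or RNP array 2 (9.82e-05), under median centring (0.0474) and with the pseudocount at the 50th percentile (0.0446). Hspa2 was on the polysome side (-0.86 ± 0.30, adjusted p = 0.0297), a call that ended without polysome array 3 (0.139) or RNP arrays 1 (0.103) or 2 (0.107), under median centring (0.118) or quantile normalization within each fraction (0.059), or with no filter (0.0528). Ldhc (0.12 ± 0.11) did not pass, except under median centring (0.0486) and quantile normalization within each fraction (0.000624). Actb was on the polysome side (-0.58 ± 0.13, adjusted p = 0.00233) except under median centring, which ended its call (-0.36, adjusted p = 0.0528).

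Of 6 chromatin condensation genes, 5 were higher in RNPs at 22 days (6 adjusted over the list alone), including the spermatid linker histone gene Hils1 (2.53 ± 0.47) and Prm3 (1.46 ± 0.36). Camera gave 0.00246, and adjusted p = 0.316 with an estimated correlation. Of the 25 sperm tail genes, 18 were higher and 1 lower, also when adjusted over the list alone, with Spata19 at 2.84 ± 0.42. Camera gave 2.25e-07, and adjusted p = 0.151 with an estimated correlation. Of the 22 spermatid regulators, 17 were higher and 0 lower (18 and 0 adjusted over the list alone), with Ube2j1 at 2.57 ± 0.23, the kinase gene Tssk2 at 2.46 ± 0.34 and Gsg1 at 2.49 ± 0.34. Camera gave 3.9e-08, and adjusted p = 0.0801 with an estimated correlation. Of the 25 Sertoli cell genes, 18 were lower and 0 higher (19 and 0 adjusted over the list alone), with Aard at -2.19 ± 0.31. Camera gave 7.64e-07, and adjusted p = 0.151 with an estimated correlation. Of 11 genes of Leydig cells, which make testosterone, 4 were lower and 0 higher, also when adjusted over the list alone, including Cyp17a1 (-2.51 ± 0.54) and Hsd3b1 (-1.99 ± 0.34). Camera gave 0.0292, and adjusted p = 0.283 with an estimated correlation.

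Of 15 peritubular and smooth muscle genes, 7 were lower and 1 higher in RNPs at 22 days (8 and 1 adjusted over the list alone), with the tropomyosin gene Tpm2 at -1.77 ± 0.34 and Tpm1 at -1.81 ± 0.41. Camera gave 0.0579 for them, 0.0375 with the pair as a block, and adjusted p = 0.464 with an estimated correlation and no block. Of 16 blood, vessel and macrophage genes, 1 was higher, H2-Ab1, and 3 were lower (0 and 1 adjusted over the list alone), among them Lyz1 (-1.40 ± 0.32), or 1 and 5 with the pair as a block. The camera test gave 0.863. Of 70 respiratory chain genes, 16 were higher and 15 lower (17 and 17 adjusted over the list alone), with Cycs, which encodes cytochrome c, at -1.97 ± 0.26 and Uqcrq at 1.29 ± 0.24. Camera gave 0.604, and the list median lay below 0 at each age while the test pointed up. Of 18 immediate early and stress-induced genes, 2 were higher, Ddit3 (2.09 ± 0.25) and Klf4 (1.06 ± 0.28), and 5 lower, also when adjusted over the list alone (2 and 8 with the pair as a block). Camera gave 0.298.

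At 22 days 5307 probe sets differed, 1955 higher in RNPs and 3352 higher on polysomes. The split was 2414 to 2602 under quantile normalization, 2818 to 2409 under median centring and 2790 to 2427 under quantile normalization within each fraction.

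In adult testes, the 7 late spermatid genes fixed beforehand were abundant in both fractions and did not differ past the threshold without the block. Prm1 averaged 10310 ± 987 in RNPs and 8743 ± 1664 on polysomes (SD, n = 3), a difference of 0.25 ± 0.80 (adjusted p = 0.828). These levels were near the top of the measured range. Prm2 (0.20 ± 0.79), Odf1 (0.29 ± 0.42), Akap4 (0.30 ± 0.44) and Smcp (0.43 ± 0.33) did not pass either. Tnp1 (0.71 ± 0.78, adjusted p = 0.494), Tnp2 (0.90 ± 0.87, 0.438), Pgk2 (0.61 ± 0.33, 0.157) and Hspa2 (-0.67 ± 0.30, 0.0825) missed the threshold and passed it with the pair as a block (0.0305, 0.0491, 0.0123 and 0.00134). Tnp1 (0.0484) and Tnp2 (0.0123) also passed with only the compared arrays, Hspa2 under quantile normalization (0.0114) and without RNP array 3 (0.0133), and Pgk2 without RNP array 1 (0.0276). Ldhc (0.15 ± 0.11) passed only under median centring (0.0326) and quantile normalization within each fraction (0.00727). Acr remained higher in RNPs (1.01 ± 0.27), and Sycp3 (-1.56 ± 0.25) and Clu (-3.97 ± 0.69) lay on polysomes. Cyp11a1, the enzyme of the first step of steroid synthesis, was 19.4-fold higher on polysomes than in RNPs (-4.28 ± 0.48, adjusted p = 6e-06). It was at 611 ± 405 against 18.5 ± 25.4 intensity units (SD, n = 3).

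Named by size on the adult RNP side were C8b (2.99 ± 0.29), the transcription factor gene Atoh8 (2.78 ± 0.49), the integrin gene Itgae, Ypel1 (2.53 ± 0.25), 2610528A11Rik and 1700093K21Rik. On the polysome side, besides Cyp11a1 and Clu, were Sparc (-4.34 ± 0.84), Gsta4 (-3.87 ± 0.45), the fatty acid binding protein gene Fabp3 (-3.82 ± 0.25) and Ldhb (-3.62 ± 0.40). Actb was at 0.04 ± 0.13, and at -0.36 under quantile normalization (adjusted p = 0.0279).

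Of the chromatin condensation genes, 0 of 6 passed in adults, also when adjusted over the list alone, and 3 were higher in RNPs with the pair as a block, among them Hils1 (0.79 ± 0.47, adjusted p = 0.195, and 0.00152 with the block). Camera gave 0.378. Of 25 sperm tail genes 9 were higher and 1 lower, also when adjusted over the list alone (12 and 5 with the pair as a block), with Spata19 at 2.10 ± 0.42 and the dynein heavy chain gene Dnah8, the exception, at -1.79 ± 0.27. Their median of 0.43 turned to -0.02 under quantile normalization, where the camera call of 0.0133 was lost (0.828), and it gave adjusted p = 0.517 with an estimated correlation. Of 22 spermatid regulators 10 were higher and 1 lower (12 and 1 adjusted over the list alone, 16 and 1 with the pair as a block), with Tssk1 at 1.61 ± 0.31. Camera gave 3.11e-05, and adjusted p = 0.251 with an estimated correlation. Of the 25 Sertoli cell genes, 17 were lower and 1 higher (18 and 1 adjusted over the list alone), with the prostaglandin D synthase gene Ptgds at -3.03 ± 0.29. Camera gave 9.03e-06, and adjusted p = 0.251 with an estimated correlation. Of the 11 Leydig cell genes, 7 were lower and 0 higher, also when adjusted over the list alone, with Cyp17a1 at -3.56 ± 0.54 and Star at -1.09 ± 0.27. Camera gave 0.0133, and adjusted p = 0.297 with an estimated correlation. Of 15 peritubular genes 9 were lower and 1 higher (9 and 2 adjusted over the list alone), with the myosin light chain gene Myl9 at -3.48 ± 0.34. Camera gave 0.0642 for these genes.

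Of 42 ribosomal protein genes 19 were higher in adult RNPs and 1 lower, also when adjusted over the list alone, with Rplp0 at 1.72 ± 0.23 and Rps7 at 1.15 ± 0.13. Camera gave 9.03e-06, 0.188 under quantile normalization, where the list median stayed above 0, and adjusted p = 0.251 with an estimated correlation. Of 42 translation factors, 5 were higher, such as Tpt1 (1.04 ± 0.12), and 12 lower, such as Gspt1 (-1.63 ± 0.29), also when adjusted over the list alone (14 and 13 with the pair as a block). Camera gave 0.654, and at each age their median was above 0 and their mean below 0. Of 37 germ cell RNA-binding protein genes, 4 were higher, among them Ybx1, a protein that coats messenger RNA (1.76 ± 0.17), and 17 lower (4 and 18 adjusted over the list alone, 7 and 23 with the pair as a block), among them Dazl (-2.75 ± 0.26) and the Piwi gene Piwil1 (-1.75 ± 0.20). Camera gave 0.0147, and adjusted p = 0.517 with an estimated correlation. The proteasome list held its direction, with 20 of 37 lower and 3 higher (25 and 3 adjusted over the list alone), for example Psmb1 at -1.92 ± 0.17. Camera gave 0.000136, and adjusted p = 0.0347 with an estimated correlation. Of 22 chaperonin and heat shock genes, 8 were lower, such as Hspe1 (-1.74 ± 0.24), and 1 higher (9 and 1 adjusted over the list alone, 12 and 2 with the pair as a block). Camera gave 0.0684, 0.0266 with the block, and adjusted p = 0.537 with an estimated correlation and no block. Of 2 epididymis genes, 1 passed, Lcn2, which encodes a secreted lipocalin (-3.20 ± 0.29, adjusted p = 1.12e-06). Wfdc15b was at 0.49 ± 0.21 (adjusted p = 0.0745, 0.0408 with the pair as a block, and called when adjusted over the list alone). Camera gave 0.469.

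**Figure D2:**
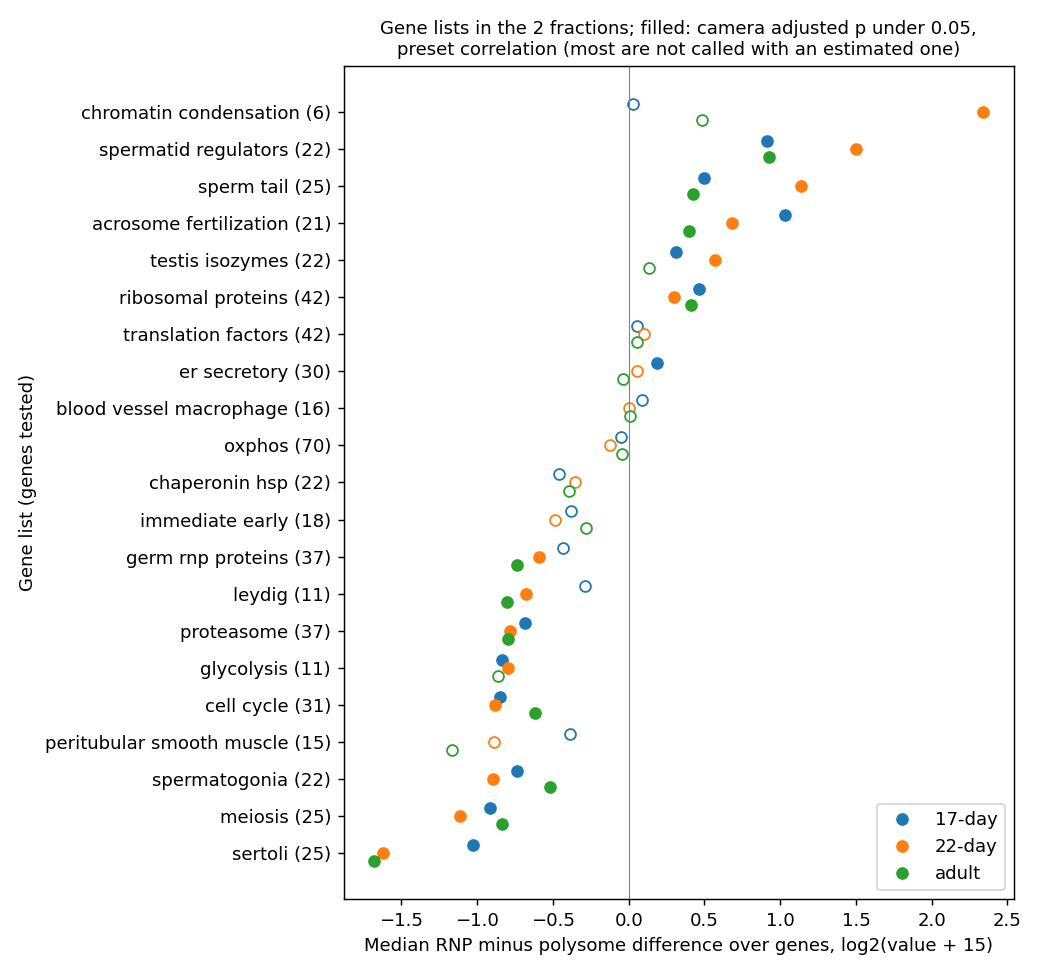
Median RNP minus polysome difference of log2(value + 15) (horizontal axis) of 21 gene lists at each age, with the number of tested genes in parentheses and filled points for camera's adjusted p under 0.05 at the preset correlation. At 22 days the sperm tail median is 1.14 and the Sertoli cell median -1.62, and the adult sperm tail median of 0.43 turns to -0.02 under quantile normalization.

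In adults 5414 probe sets differed, 1772 higher in RNPs and 3642 higher on polysomes. The split was 2354 to 2846 under quantile normalization, 2728 to 2652 under median centring and 2825 to 2650 under quantile normalization within each fraction. The median difference over all tested probe sets was -0.09, -0.13 and -0.17 at 17 days, 22 days and in adults, and other scalings moved it to at most 0.04, 0.08 and 0.05. Camera compares a list with the other genes and so is relative to this median. With only the adult arrays in the model the count was 2949, and the call of Acr was lost (adjusted p = 0.0687). The count of 5414 thus leans on a spread shared with the arrays of the other ages.

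The fractions were compared across ages by the overlap of calls, which share no arrays. At all 3 ages, 1007 probe sets were higher in RNPs and 1563 higher on polysomes. Between 17 and 22 days, 1344 were on the RNP side and 1922 on the polysome side at both ages, where independent lists would give 246 and 541. Only 4 were opposite, where such lists would give 738. Between 22 days and adults the counts were 1278, 2614 and 4 (246, 868 and 928 for independent lists), and between 17 days and adults 1086, 1641 and 24 (223, 588 and 745). The log2 differences correlated across probe sets with r of 0.851, 0.864 and 0.728 in these comparisons (Spearman 0.842, 0.864 and 0.724), which describes genes that are not independent replicates.

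RNA quality was compared between the fractions with the control probe sets at the ends of the actin and Gapdh transcripts. The 3' minus 5' log2 difference of actin was higher in RNP than in polysome arrays by 0.48 at 17 days (two-sided exact permutation p = 0.1, the smallest possible), by 0.16 at 22 days (0.5) and by 0.31 in adults (0.1). It was higher in RNPs in each pair of arrays at each age, by 0.23, 0.13 and 0.13 in the 22-day pairs (exact permutation p within pairs of 0.25 at each age, the smallest possible with 3 pairs). The lists on the RNP side at each age thus lay in the fraction with the higher actin value. The mean actin value also fell with age, from 1.37 to 0.85 and 0.79 in RNPs and from 0.88 to 0.69 and 0.48 on polysomes. Comparisons of ages within a fraction are thus between arrays that differ in it. For Gapdh the differences were 0.12, 0.09 and 0.32 (exact p of 0.7, 0.8 and 0.4). The mean log2 signal of the poly-A control transcripts was lower in RNP arrays by values of -0.02, -0.52 and -1.24 (exact p of 1, 0.5 and 0.3), in each pair at 22 days and in adults (exact p within pairs of 0.25 at both). Its geometric means were highest in both arrays of 17-day replicate 2 (335 and 337) and, for polysomes, next highest in adult replicate 1 (219).

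Changes in distribution between 17 and 22 days were tested as differences of the RNP minus polysome value. In the ratio contrasts a move towards RNPs or polysomes is a change of that value. It does not show a transfer of transcript between the fractions. Limma called 0 of 14066 probe sets, with 817 at an unadjusted p under 0.05, where 703 would be given by chance. The count was 203 with replicate pairs as a block, 146 higher and 57 lower in RNPs at 22 days. With the block, 5 of 7 late spermatid genes fixed beforehand moved towards RNPs, Odf1 by 2.73 ± 0.28 (adjusted p = 0.000548, and 0.277 without the block), Tnp1 by 2.65 ± 0.36 (0.00345, and 0.791), Prm1 by 2.38 ± 0.38 (0.00609, and 0.86), Prm2 by 2.22 ± 0.34 (0.00509, and 0.875) and Akap4 by 1.87 ± 0.25 (0.00345, and 0.586). Tnp2 (2.10) and Smcp (1.21) did not pass with the block (0.0588 and 0.0898). Without the block, Odf1 (0.0123), Tnp2 (0.03) and Tnp1 (0.041) passed when the RNP array of 22-day replicate 2 was left out. The 17-day signals of the 5 genes were near the floor, with Odf1 at 2.73 and 6.03 intensity units on polysomes and in RNPs, so the 17-day side of this change carries little information.

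Of the 22 lists, 6 passed camera between 17 and 22 days, and 0 of their members passed over all genes. The chromatin condensation list was called towards RNPs (median 2.30, adjusted p = 5.21e-07, and adjusted p = 0.63 with an estimated correlation). Of its genes, 1 of 6 was higher adjusted over the list alone and 5 with the pair as a block, such as Hils1 at 2.53 (adjusted p = 0.378, and 0.000506 with the block). All 6 were below the filter value in both fractions at 17 days, so this call largely restates their difference at 22 days. The sperm tail list was called upwards (0.0338, and adjusted p = 0.935 with an estimated correlation), with a median of -0.09 against a mean of 0.44. It had 6 higher and 1 lower adjusted over the list alone, and 6 and 0 with the pair as a block. It kept the call under only 1 of the 3 other scalings (highest adjusted p = 0.63). The Sertoli cell (median -0.58, adjusted p = 0.00578), Leydig cell (-0.55, 0.0242), ribosomal protein (-0.18, 0.0218) and germ cell RNA-binding protein (-0.23, 0.0466) lists moved towards polysomes, with 0 members past the threshold adjusted over each list alone. With the pair as a block 1 Sertoli cell gene and 1 gene of an RNA-binding protein were lower. They gave adjusted p = 0.935, 0.819, 0.935 and 0.935 with an estimated correlation, and the last of these calls was also lost under another scaling (0.0595). Without the RNP array of 22-day replicate 2 the count was 91, and without the polysome array of 17-day replicate 2 it was 1.

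Between 22 days and adults, the genes named by size that moved towards RNPs were Cdkn1c, an inhibitor of cyclin-dependent kinases (3.44 ± 0.51, adjusted p = 0.00778), the pyruvate kinase gene Pkm (2.06 ± 0.36, 0.021) and the quinone reductase gene Nqo2 (1.86 ± 0.32, 0.021). Cdkn1c rose in adult RNPs to 551 ± 195 intensity units from 22.7 ± 14.6, with polysomes at 103 ± 35.4 in adults (SD, n = 3). Towards polysomes moved Agt, the angiotensin precursor (-3.38 ± 0.54, 0.0115), Ptgds (-2.89 ± 0.37, 0.00265), the kallikrein genes Klk1b27 (-2.79 ± 0.49, 0.0222) and Klk1b21 (-2.51 ± 0.45, 0.0222), and the apolipoprotein gene Apoc1 (-2.65 ± 0.44, 0.0175). The Ptgds probe set was at 33.1 ± 9.59 on 22-day polysomes and at 719 ± 212 on adult polysomes, against 26.0 ± 8.85 in 22-day and 69.6 ± 28.9 in adult RNPs (SD, n = 3). These 5 genes averaged below the filter value of 51.6 in both fractions at 22 days, so the 22-day side of their change carries little information. The Klk1b genes are close paralogs whose probe sets may share transcripts, so their identity is uncertain.

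Limma called 16 probe sets between 22 days and adults, 5 towards RNPs and 11 towards polysomes, with 783 at an unadjusted p under 0.05. The split was 6 to 24 under quantile normalization. With replicate pairs as a block the count was 130 (27 and 103). With the block, Odf1 (-2.66 ± 0.28, adjusted p = 0.000671, and 0.139 without the block), Pgk2 (-2.08 ± 0.26, 0.00223, and 0.143), Prm2 (-2.21 ± 0.34, 0.00996, and 0.909), Tnp1 (-1.99 ± 0.36, 0.0189, and 0.964), Prm1 (-2.02 ± 0.38, 0.0232, and 0.964), Akap4 (-1.51 ± 0.25, 0.0132, and 0.838) and Smcp (-1.54 ± 0.32, 0.0392, and 0.456) moved towards polysomes. Tnp2 (-1.21) did not pass with the block (0.314). The adult side of the Prm1 and Prm2 values rests on levels near the top of the measured range, where a difference can be compressed, so the size of their shift is uncertain. Odf1 and Pgk2 were also called without the block under quantile normalization (-3.14 and -2.43, adjusted p = 0.0289 for both). Odf1 was called as well without polysome array 1 (0.0422) or RNP array 2 (0.0186) of 22 days, and Pgk2 without polysome adult array 1 (0.0311). Pgk2 was called, and Pkm (0.0987) and Apoc1 (0.0643) were not, without the 4 arrays of 17-day replicate 2 and adult replicate 1 (0.0106 for Pgk2). The count was 7 with only the compared arrays, where Pkm (0.172), Nqo2 (0.115), Klk1b27 (0.115), Apoc1 (0.0902) and Klk1b21 (0.148) lost their calls, and 25 with no filter. It was 9 among probe sets above the 50th percentile at both ages, a restriction chosen after the data had been seen. With a pseudocount of 1 the calls of Agt (0.207), Klk1b27 (0.702) and Klk1b21 (0.119) ended, and with the filter at the 75th percentile those of Klk1b27 (0.196) and Klk1b21 (0.0634). The count was 8 without the polysome array of 22-day replicate 2, 4 without the RNP array of 22-day replicate 3, 26 without the RNP array of adult replicate 1 and 9 without that of adult replicate 3. The calls of Cdkn1c and Ptgds held with each array left out, while those of the other 6 named genes ended without at least 1 array (adjusted p in parentheses). Calls were lost without polysome 22-day array 1 by Pkm (0.0661), Nqo2 (0.0657), Klk1b27 (0.0657) and Klk1b21 (0.0701) and without polysome 22-day array 2 by Pkm (0.0784), Nqo2 (0.0593), Klk1b27 (0.0784) and Apoc1 (0.062). They were also lost without polysome 22-day array 3 by Nqo2 (0.0614) and Klk1b21 (0.0941) and without RNP 22-day array 1 by Klk1b21 (0.0757). Others were lost without RNP 22-day array 2 by Pkm (0.0532) and without RNP 22-day array 3 by Pkm (0.0656), Nqo2 (0.0656), Agt (0.0532), Klk1b27 (0.0794), Apoc1 (0.0656) and Klk1b21 (0.0656). Calls ended as well without polysome adult array 2 by Pkm (0.0599) and without polysome adult array 3 by Klk1b27 (0.1) and Klk1b21 (0.0898). More were lost without RNP adult array 2 by Nqo2 (0.0559), Klk1b27 (0.0693) and Klk1b21 (0.0798) and without RNP adult array 3 by Pkm (0.0578), Nqo2 (0.0578), Klk1b27 (0.0644), Apoc1 (0.0578) and Klk1b21 (0.0682).

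Of the lists, 5 passed camera between 22 days and adults. Sperm tail genes moved towards polysomes (median -0.63, adjusted p = 1.16e-08, and adjusted p = 0.335 with an estimated correlation). Of them, 0 of 25 passed the threshold over all genes and 5 were lower adjusted over the list alone or with the pair as a block, such as Odf2 (-1.52 ± 0.42, adjusted p = 0.34, and 0.00996 with the pair as a block). Chromatin condensation genes did so too (median -1.86, adjusted p = 0.000411, and adjusted p = 0.335 with an estimated correlation). Here 0 of 6 passed the threshold, 1 was lower adjusted over the list alone and 5 were lower with the pair as a block. Spermatid regulators (median -0.45, adjusted p = 0.00137) and germ cell isozymes (-0.20, 0.004) moved the same way, each with adjusted p = 0.335 with an estimated correlation. Over all genes 0 passed, and adjusted over the list alone 2 of the former were lower, and 1 of the latter was higher and 2 lower. With the pair as a block 4 of each were lower. The ribosomal protein list was called towards RNPs (median 0.20, adjusted p = 0.00296, and adjusted p = 0.462 with an estimated correlation), a call lost under quantile normalization (0.108). The immediate early list passed only with the pair as a block (0.0449, and 0.064 without it). With an estimated correlation and no block 0 of the 22 lists passed, the smallest adjusted p being 0.335.

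Between 17 days and adults, more transcripts changed their distribution. Tubb6, a beta tubulin, moved towards RNPs by 3.57 ± 0.49 (adjusted p = 0.00238). Its polysome level was 80.7 ± 3.08 at 17 days and 80.5 ± 27.4 in adults, while its RNP level was 12.7 ± 4.85 and 304 ± 49.9 (SD, n = 3). The change thus lay in its RNP level. Also towards RNPs moved Cdkn1c (adjusted p = 0.00876), the endocytic scaffold gene Itsn2 (2.43 ± 0.39, adjusted p = 0.00553), App, the amyloid precursor protein (2.35 ± 0.49), the protein kinase C gene Prkcd (2.19 ± 0.41) and Pccb, a subunit of propionyl-CoA carboxylase (2.10 ± 0.43). Towards polysomes moved Tesc, a calcium-binding protein (-3.46 ± 0.61, adjusted p = 0.00876), Mmd2 (-3.40 ± 0.49), Agt (-3.32 ± 0.54), Bscl2 (-3.24 ± 0.71), Ptgds (-2.94 ± 0.41), Lcn2 (-2.83 ± 0.41), Thrsp (-2.75 ± 0.41), the scaffold gene Iqgap1 (-2.73 ± 0.47) and Pgk2 (-2.40 ± 0.47, adjusted p = 0.0187). Mmd2 was at 433 ± 93.4 on polysomes and 404 ± 42.9 in RNPs at 17 days, and at 328 ± 126 and 14.2 ± 2.60 in adults (SD, n = 3). Its move thus came with a lower RNP level and no higher polysome level.

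The other genes named by size were Ccdc93, Epb41l3 (2.47 ± 0.55), Dpysl4 (2.14 ± 0.44) and 1190005I06Rik (2.12 ± 0.43) towards RNPs, and Klk1b21 and Klk1b27 (-3.05 ± 0.49), of uncertain identity as above, towards polysomes. Of the 21 named genes, 13 were called with each array left out, and the others lost the call without some array (adjusted p in parentheses). Calls were lost without polysome 17-day array 1 by Ccdc93 (0.0609), Epb41l3 (0.0807), App (0.0686), Dpysl4 (0.0684), 1190005I06Rik (0.0609), Pccb (0.0609), Bscl2 (0.0981) and Pgk2 (0.0512) and without polysome 17-day array 2 by Epb41l3 (0.0504), App (0.0504) and Dpysl4 (0.0504). They were also lost without polysome 17-day array 3 by Ccdc93 (0.0637), Epb41l3 (0.0972), Dpysl4 (0.0711), 1190005I06Rik (0.0563), Pccb (0.0646), Bscl2 (0.0861) and Pgk2 (0.0676) and without RNP 17-day array 1 by Epb41l3 (0.0563), App (0.0721), Dpysl4 (0.0593), 1190005I06Rik (0.0615), Pccb (0.0631), Bscl2 (0.0688) and Pgk2 (0.0533). Others were lost without RNP 17-day array 2 by Epb41l3 (0.0735) and Bscl2 (0.0696) and without RNP 17-day array 3 by App (0.0762), Dpysl4 (0.0616), Pccb (0.0681), Bscl2 (0.0762) and Pgk2 (0.0506). Calls ended as well without polysome adult array 1 by Epb41l3 (0.0503) and without polysome adult array 3 by Epb41l3 (0.0593), Dpysl4 (0.0544), Bscl2 (0.0673) and Pgk2 (0.0511). More were lost without RNP adult array 2 by Epb41l3 (0.0692) and Bscl2 (0.0648) and without RNP adult array 3 by Epb41l3 (0.0692) and App (0.0505). The 17-day polysome level of Bscl2 was 80.9 ± 104 (SD, n = 3). Lcn2 was at 11.2 and 5.07 intensity units on polysomes and in RNPs at 17 days, near the floor, and at 1213 and 126 in adults. Agt, Klk1b27, Klk1b21, Thrsp, Ccdc93 and 1190005I06Rik were also below the filter value in both fractions at 17 days, and Dpysl4 in adults. With a pseudocount of 1 the calls of Lcn2 (0.114), Klk1b27 (0.0952), Ccdc93 (0.0778), Dpysl4 (0.111) and 1190005I06Rik (0.0983) ended. With only the compared arrays those of Epb41l3 (0.096), Dpysl4 (0.0588), Bscl2 (0.0888) and Pgk2 (0.0558) ended. Epb41l3 also lost its call with no filter (0.0569), Pgk2 with the pseudocount at the 50th percentile (0.0555) and 1190005I06Rik without the 4 arrays of 17-day replicate 2 and adult replicate 1 (0.0857).

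Limma called 164 probe sets (140 genes) between 17 days and adults, 57 towards RNPs and 107 towards polysomes, with 64 and 77 under median centring. With replicate pairs as a block the count was 1567 (417 and 1150), and all 164 were in it. Without the 4 arrays of 17-day replicate 2 and adult replicate 1, left out after the data had been seen, it was 374 (96 and 278), and with only the compared arrays 83. The count was 49, 53, 59, 103 and 60 without the 17-day arrays of polysome replicates 1 and 3 and RNP replicates 1, 2 and 3, 272 and 84 without the adult polysome arrays of replicates 1 and 3, and 328 without the adult RNP array of replicate 1. This contrast and that of 22 days and adults use the same adult arrays, so calls in both are not independent. Of the 22 lists, 0 passed camera, with the smallest adjusted p at 0.0899 for Leydig cell genes, where Cyp11a1 was at -2.46 ± 0.68 (adjusted p = 0.085, and 0.0219 with the pair as a block). Single members passed: 2 of 25 sperm tail genes were lower (4 adjusted over the list alone, 3 higher and 11 lower with the pair as a block), Odf2 (-1.94 ± 0.42) and Ropn1l (-1.01 ± 0.21). Of 22 isozymes 3 were lower, also when adjusted over the list alone, Pgk2, Pgam2 (-1.44 ± 0.31) and the calcineurin subunit gene Ppp3cc (-1.60 ± 0.32). Of 22 spermatogonia genes 1 was higher, Esx1 (1.49 ± 0.31; 3 higher and 3 lower adjusted over the list alone and with the pair as a block).

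**Figure D3:**
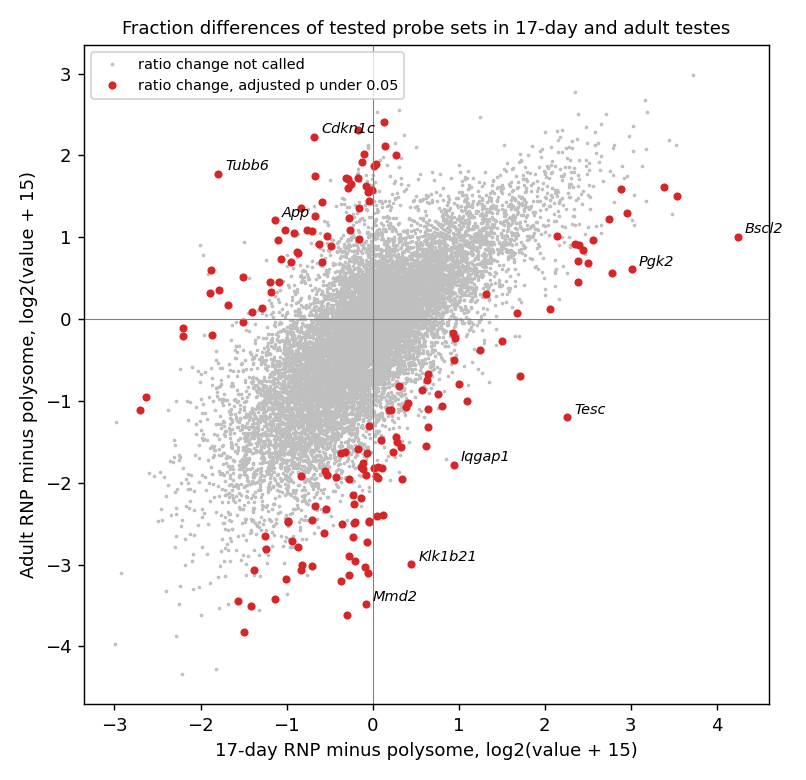
RNP minus polysome difference of log2(value + 15) in 17-day testes (horizontal axis) against that in adult testes (vertical axis) for the 14066 tested probe sets, with the 164 called ratio changes in red. Tubb6 lies at -1.80 and 1.77, and Tesc at 2.26 and -1.20.

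A switch of fraction, called on 1 side at 17 days and on the other in adults, was found for 22 probe sets, 12 from the polysome to the RNP side and 10 the other way. The sides rest on the authors' scale, since the position of 0 depends on the scaling. The poly-A controls differed between fractions by -0.02 at 17 days and -1.24 in adults. A switch thus does not show which fraction held more of a transcript. Tubb6 went from -1.80 ± 0.35 at 17 days through 0.44 at 22 days to 1.77 ± 0.35 in adults. Both subunit genes of propionyl-CoA carboxylase switched to RNPs, Pccb from -1.01 ± 0.30 to 1.09 ± 0.30 and Pcca from -0.88 ± 0.28 to 0.82 ± 0.28. So did App (-1.14 ± 0.35 to 1.21 ± 0.35), Prkcd (-0.83 to 1.36), the histone deacetylase gene Hdac5 (-0.91 to 1.05), the nuclear receptor gene Nr4a1 (-0.87 to 0.80) and Cxxc5 (-0.77 to 1.09). To polysomes switched Tesc (2.26 ± 0.43 to -1.20 ± 0.43), Iqgap1 (0.94 ± 0.33 to -1.78 ± 0.33), the small GTPase genes Rhou (0.65 to -1.09), Rab12 (0.63 to -0.74) and Rab33b (0.58 to -0.87), the RNA-binding protein gene Khdrbs3 (0.64 to -0.67) and both probe sets of Pgap2 (1.10 to -1.01 and 1.01 to -0.79). For Serp1 (0.80 to -1.06) another probe set was higher in adult RNPs. With replicate pairs as a block 120 probe sets switched, 57 to RNPs and 63 to polysomes, and all 22 were among them. With only the compared arrays the number was 13. It was 6, 14 and 5 without the 17-day polysome arrays of replicates 1, 2 and 3, 8, 13 and 8 without the 17-day RNP arrays of replicates 1, 2 and 3, and 14 without the adult polysome array of replicate 3.

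Ages were also compared within each fraction. On polysomes, between 17 and 22 days, Tsga8 (4.47 ± 0.42), Cabyr, a calcium-binding protein of the sperm tail, Smcp (adjusted p = 3.98e-06) and Krt88 (3.77 ± 0.43) rose. Smpd2 (-2.38 ± 0.27), Acy1 (-1.62 ± 0.23), Pdlim4 (-1.43 ± 0.38, adjusted p = 0.0496) and Tpm2 (-1.35 ± 0.34, 0.038) fell. The calls of Pdlim4 and Tpm2 ended without any of the 6 arrays, at adjusted p of 0.189, 0.076, 0.18, 0.148, 0.169 and 0.0538 and of 0.148, 0.0887, 0.0961, 0.0954, 0.0581 and 0.17 for 17-day arrays 1 to 3 and then 22-day arrays 1 to 3. Pdlim4 also lost its call under all 3 other scalings (0.0722, 0.0593 and 0.0754), and Pdlim4 and Tpm2 with a pseudocount of 1 (0.161 and 0.0537) and with no filter (0.0732 and 0.0599). In all 385 probe sets changed, 340 of them higher at 22 days, and 935 (741 higher) without the 4 arrays of 17-day replicate 2 and adult replicate 1. The count was 178, 177, 155 and 242 without the arrays of 17-day replicates 1 and 3 and 22-day replicates 1 and 3. Of the chromatin condensation genes 2 of 6 rose (6 adjusted over the list alone; 2.5e-06, and adjusted p = 0.168 with an estimated correlation). Other lists rose on polysomes with both correlations, 14 of 25 sperm tail genes (24 adjusted over the list alone; 1.29e-30, and adjusted p = 0.00604 with an estimated correlation), including Tekt2 (2.53) and Spag4 (2.83). So did 10 of 21 acrosome genes (19 adjusted over the list alone; 6.66e-19, and adjusted p = 0.0126 with an estimated correlation), 10 of 22 spermatid regulators (17 adjusted over the list alone; 5.46e-19, and adjusted p = 0.00604 with an estimated correlation) and 7 of 22 isozymes (11 adjusted over the list alone; 1.09e-09, and adjusted p = 0.00604 with an estimated correlation).

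On polysomes between 22 days and adults, the genes of sperm chromatin rose, Prm2 by 6.23 ± 0.79 (adjusted p = 3.03e-05), Prm1 by 5.83 ± 0.80 (7.84e-05) and Tnp1 (8.85e-05). With them rose Oxct2a, a ketone body enzyme of germ cells. Cnn3 (-2.08 ± 0.51, adjusted p = 0.0168), the collagen gene Col4a1 (-1.90 ± 0.35), Itsn1 (-1.86 ± 0.40) and Oga (-1.84 ± 0.47, 0.0192) fell. The call of Cnn3 ended without polysome 22-day arrays 1 (0.094) or 2 (0.0899) or adult array 1 (0.0805), and that of Oga without polysome 22-day array 2 (0.0776) or adult array 1 (0.0652). Cnn3 also lost its call with a pseudocount of 1 (0.0549), Oga with only the compared arrays (0.0965) and Itsn1 without the 4 arrays of 17-day replicate 2 and adult replicate 1 (0.0607). In all 1013 probe sets changed, 685 higher and 328 lower in adults, with 512 in all without the polysome array of 22-day replicate 2 and 586 with only the compared arrays. All 6 chromatin condensation genes rose, also when adjusted over the list alone (1.85e-12, and adjusted p = 0.0456 with an estimated correlation), as did 16 of 25 sperm tail genes (18 higher and 1 lower adjusted over the list alone; 1.2e-14, and adjusted p = 0.0456 with an estimated correlation). Of 31 cell cycle genes 5 fell and 0 rose (8 and 0 adjusted over the list alone; 0.000117, and adjusted p = 0.0456 with an estimated correlation), such as Mcm3 (-1.17). Lcn2 rose 36.1-fold on polysomes (5.17 ± 0.29, adjusted p = 7.05e-09) and Ptgds by 4.33 ± 0.29. The epididymis list of 2 passed (0.00871, and adjusted p = 0.0608 with an estimated correlation), a call that rests on Lcn2 alone, since Wfdc15b was at -0.01 ± 0.21 (adjusted p = 0.987). Of 11 Leydig cell genes 3 rose and 0 fell (4 and 1 adjusted over the list alone; 0.0227, and adjusted p = 0.327 with an estimated correlation), including Hsd17b3 (1.88 ± 0.39) and Cyp17a1 (1.83 ± 0.54).

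In RNPs between 17 and 22 days, Hils1 (5.99 ± 0.47), Odf1 (5.69 ± 0.42), Dpysl3 (5.18 ± 0.45) and Smcp (5.04 ± 0.33) rose. Cox8a (-3.09 ± 0.49), Tesc (-2.74 ± 0.43), Nkain1 (-2.42 ± 0.30) and Gsta4 fell. In all 2243 probe sets changed, 778 higher and 1465 lower at 22 days. The splits were 832 to 991 under quantile normalization, 937 to 1019 under median centring and 892 to 1082 under quantile normalization within each fraction. The count was 1167, 1365, 858 and 1049 without the RNP arrays of 17-day replicates 1 and 3 and 22-day replicates 1 and 3. Of the lists, 17 of 25 sperm tail genes rose (20 adjusted over the list alone; 3.07e-20, and adjusted p = 0.0232 with an estimated correlation), and all 6 chromatin condensation genes did, also when adjusted over the list alone (2.42e-09, and adjusted p = 0.083 with an estimated correlation). Of 42 ribosomal protein genes 12 fell and 0 rose (15 and 0 adjusted over the list alone; 1.53e-05, and adjusted p = 0.226 with an estimated correlation). Of 25 Sertoli cell genes 8 fell and 0 rose (11 and 0 adjusted over the list alone; 0.000211, and adjusted p = 0.361 with an estimated correlation), such as Wt1 (-1.26).

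In RNPs between 22 days and adults, Nudt16l2 (5.50 ± 0.31), the spermatid kinase gene Tssk6 (5.35 ± 0.49), the glutamine synthetase gene Glul (4.39 ± 0.46) and Oxct2a (4.28 ± 0.45) rose. Senp1 (-2.30 ± 0.42), Oga (-2.26 ± 0.47), Mmd2 and Dazl (-2.18 ± 0.36) fell. In all 1968 probe sets changed, 857 higher and 1111 lower in adults, and 916 to 802 under quantile normalization. Without the RNP array of 22-day replicate 2 the count was 666, and with only the compared arrays it was 958. All 6 chromatin condensation genes rose, also when adjusted over the list alone (6.73e-07, and adjusted p = 0.218 with an estimated correlation). Of 22 spermatid regulators 9 rose and 1 fell (10 and 1 adjusted over the list alone; 6.71e-06, and adjusted p = 0.218 with an estimated correlation). Of 37 germ cell RNA-binding protein genes 8 fell and 0 rose (10 and 1 adjusted over the list alone; 0.00591, and adjusted p = 0.578 with an estimated correlation). Of the germ cell isozymes 6 rose and 1 fell, also when adjusted over the list alone (0.0257, and adjusted p = 0.375 with an estimated correlation). Under quantile normalization over all arrays and within each fraction this call was lost (0.408 and 0.398) and the median of 0.14 turned to -0.05 and -0.06. It was also lost with no filter (0.0717) and with only the compared arrays (0.0509).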

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

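A test of the difference between ages drew attention to the changes in the RNP to polysome ratio below, and a control probe set outside the gene comparisons drew attention to the repeat signal. In this part, the 2 tests of scaling between arrays and the 2 floor tests by direction were chosen after the data had been seen, and the other tests were fixed before.

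Between 22 days and adults the ratio differed for 16 probe sets. The genes named by the rule moved towards RNPs for Cdkn1c (log2 3.44), Pkm (2.06) and Nqo2 (1.86), and towards polysomes for Agt (-3.38), Ptgds (-2.89), Klk1b27 (-2.79), Apoc1 (-2.65) and Klk1b21 (-2.51). The 5 towards polysomes were below the filter value in both fractions at 22 days, so that side of their change carries little information.

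Between 17 days and adults the ratio differed for 164 probe sets. Towards RNPs moved Tubb6 (3.57), Cdkn1c (2.91), Ccdc93 (2.49), Epb41l3 (2.47), Itsn2 (2.43), App (2.35), Prkcd (2.19), Dpysl4 (2.14), 1190005I06Rik (2.12) and Pccb (2.10). Towards polysomes moved Tesc (-3.46), Klk1b21 (-3.45), Mmd2 (-3.40), Agt (-3.32), Bscl2 (-3.24), Klk1b27 (-3.05), Ptgds (-2.94), Lcn2 (-2.83), Thrsp (-2.75), Iqgap1 (-2.73) and Pgk2 (-2.40).

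For the 164 changes between 17 days and adults, a transcript absent at an age could give a change without a shift between fractions. Of these probe sets, 38 (23.2%, 95% interval 17.0% to 30.4%) were at or below the 50th percentile of all values in both fractions at an age, which argues against this as the cause of most of the set, while for those 38 it stays open. The share was 14.0% (95% interval 8.06% to 22.1%) among changes towards polysomes, below the preset 50%. Among changes towards RNPs it was 40.4% (27.6% to 54.2%), which does not exclude 50% and lies above the 19.5% of probe sets not called, so a floor effect and a shift between fractions cannot be told apart for this part. Under the least favourable of 3 other scalings 81.1% of calls stayed in the same direction, which had been set as enough to argue against scaling between arrays. These scalings moved the median change only from -0.14 to between -0.07 and -0.06, while all 164 changes were at least 2-fold. The poly-A controls differed between fractions by -0.02 at 17 days and -1.24 in adults, and no scaling to them was run. A larger effect of scaling could therefore not be excluded and stays open. A biological difference with age, which includes another mixture of cells in the testis, was not tested and stays open.

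The B1 control, a probe set for a repeat found in many transcripts, was higher in RNPs by log2 2.07 at 17 days, 2.40 at 22 days and 3.33 in adults, in each pair of arrays (exact permutation p = 0.1 at each age, the smallest possible with 3 arrays a fraction). Scaling between arrays of the 3 other kinds tried is argued against, since the lowest difference under them was 1.73. No scaling to the poly-A controls was run. RNA leaked from nuclei could carry such repeats, and nuclear noncoding RNAs above the filter had a median adult difference of 0.11, but only 1 of them, Meg3, averaged over 103.2, where 3 were needed. Markers near the floor decide nothing, so leakage and its absence cannot be told apart, although the value had been set beforehand as enough to argue against it. The control for another repeat, B2, was also higher in RNPs in each pair but differed less. In adults B2 lay at 5102 to 6676 intensity units in RNPs and 3506 to 5201 on polysomes, and B1 at 4501 to 7035 and 394 to 879. A difference between RNPs and polysomes in transcripts that carry the B1 repeat is the biological explanation, and it was not tested.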

How the results depend on the processing

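Of 179 values of named genes, 126 kept their side of the threshold in every setting, without a called value changing direction, as did 113 of 220 values of gene lists. A change of direction was not counted for values that passed neither in the main fit nor in the setting. The direction of camera reversed for none of the lists called both in the main fit and in the setting. Under other scalings, though, the medians of adult sperm tail genes (-0.02) and of isozymes in RNPs between 22 days and adults (-0.06) turned negative. The 50th percentile limit on ratio counts and the omission of 4 arrays were chosen after the data had been seen. Of the 85 list values called in the main fit, 69 lost the call with an estimated correlation. Of 117 called values of named genes 25 lost the call without at least 1 array. The values of named genes that reversed with a call in the main fit or the setting, under quantile normalization, were Ldhc at 17 days (-0.18) and Actb in adults (-0.36), and the cause was not tested. The ratio count of 22 days and adults was 30 under quantile normalization and 25 with no filter, and that of 17 and 22 days was 1 with the pseudocount at the 50th percentile, and the cause was not tested. With only the compared arrays, the counts were 2949 for adult fractions, 1, 7 and 83 for the ratios of 17 and 22 days, 22 days and adults, and 17 days and adults, 586 on polysomes and 958 in RNPs for 22 days and adults, and 13 switches. Of the fraction calls, this setting kept 3878 of 4044 at 17 days, 5174 of 5307 at 22 days and 2935 of 5414 in adults. Fewer arrays alone thus do not account for the adult loss. The lowest correlations between replicates, 0.859 on polysomes and 0.914 in RNPs, were in adults, so the adult count leans on a spread shared with the other ages.

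With replicate pairs as a block the counts were 6108 for 17-day fractions, 203, 130 and 1567 for the ratios in the same order, and 120 switches, and apart from the values printed beside the results the block changed no other call of a gene fixed beforehand or named by size, nor of a list, in the fractions and ratios. It changed calls of list members that the report does not name there, such as Cyp17a1 at 17 days (0.0772, and 0.0149 with the block). Replicate numbers do not pair arrays of different ages. With those numbers as a block the age contrasts gave 329 and 890 on polysomes and 1987 and 1616 in RNPs.

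Restricted to probe sets above the 50th percentile at both ages, 9 ratio changes between 22 days and adults remained. Without the 4 arrays of 17-day replicate 2 and adult replicate 1, 374 ratio changes were called between 17 days and adults and 935 probe sets changed on polysomes between 17 and 22 days, and the cause was not tested.

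With single arrays left out the counts ran from 2628 to 3692 for 17-day fractions, from 0 to 91, from 4 to 26 and from 49 to 328 for the ratios in the same order, from 155 to 462 and from 512 to 1144 on polysomes, from 858 to 2398 and from 666 to 1841 in RNPs, and from 5 to 33 for switches. Signal over background limits genes with values near 51.6, where a difference between fractions is compressed.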

Other observations

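Some gene groups not described above changed with age within a fraction. In RNPs between 17 and 22 days, 10 of 21 acrosome genes rose and 0 fell (14 and 0 adjusted over the list alone), and camera gave 1.04e-09, and adjusted p = 0.083 with an estimated correlation. Of 22 spermatogonia genes 8 fell and 1 rose there (10 and 2 adjusted over the list alone), with Uchl1 at -1.71 and Dmrt1 at -1.75. Camera gave 0.00827 for them, and adjusted p = 0.361 with an estimated correlation. Of 15 peritubular genes 6 fell and 1 rose (11 and 1 adjusted over the list alone), and camera gave 0.00882, and adjusted p = 0.361 with an estimated correlation.

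On polysomes between 22 days and adults, 8 of 22 germ cell isozymes rose and 1 fell (9 and 1 adjusted over the list alone), with the sperm glyceraldehyde phosphate dehydrogenase gene Gapdhs at 4.54 ± 0.36. Camera gave 7.02e-05, and adjusted p = 0.0456 with an estimated correlation. Of 25 meiosis genes 2 rose and 1 fell (2 and 2 adjusted over the list alone), with Rec8 at 1.85, and camera called the list downwards at 0.0403, and adjusted p = 0.476 with an estimated correlation.

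Probe sets of a single gene were sometimes called in opposite directions in adults, in 58 of 1577 pairs of called probe sets (43 genes). Of the opposite pairs 24.1% held a probe set of the kind shared between genes or transcripts, against 50.6% of the pairs in the same direction. This had been set beforehand as enough to argue against cross-hybridizing probe sets. Such probe sets can, however, share sequence with the other probe sets of their gene, which favours the same direction. The comparison therefore cannot decide, and cross-hybridization stays open. False calls at this threshold stay open, since 5% of the pairs would be 79. At all 3 ages, however, Pnkd (-2.11 and 1.41 in adults) and 4833420G17Rik had opposite probe sets. Transcript forms that differ between fractions are the biological explanation, and they were not tested.

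Fraction and age labels were also exchanged among the arrays of each comparison, in the 10 ways to split 6 arrays into 3 and 3, too few for a share under 0.05. The other splits mix arrays that differ by fraction or age. This raises the spread in the model and lowers their counts, so they do not show what chance alone would give. For the fractions, 1 of 10 splits, the real one, gave as many calls at each age, and the highest other numbers of calls were 0 at 17 days, 14 at 22 days and 519 in adults. Among splits that part all 3 pairs the highest other numbers were 0, 0 and 1. For the ratio changes, all 10 splits gave as many calls between 17 and 22 days, where the real count is 0, and 1 of 10 did so between 22 days and adults and between 17 days and adults, with 0 as the highest other number. For the age contrasts it was 1 of 10 in each, with highest other numbers of 119 and 2 on polysomes and 0 and 0 in RNPs, in order of age.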
